A study of Mus musculus with 11 samples.

How the data were processed

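RNA of 11 mouse samples was sequenced: 3 wild-type and 3 Ebf1 heterozygous progenitor B cell samples from bone marrow, column purified from pools of 3 to 7 mice, and 5 lymph node leukemia samples of 1 mouse each. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to library size) for 23071 gene identifiers. Per the submitters' processing notes, BWA 0.7.12 was listed for the wild-type and leukemia samples and TopHat2 with Cufflinks for the Ebf1 heterozygous samples, with mouse build mm10 (GRCm38). The tool that counted reads and the gene annotation are not given in the sources used here. A difference in alignment would fall together with the Ebf1 heterozygous group.

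The FPKM values of all 17380 genes above 0 were whole numbers of reads, within 0.001 read, once a whole-number gene length and a library total were found for them. Library totals in units of 1e6 reads were 11.09, 11.86 and 14.49 in wild type, 15.31, 11.21 and 12.59 in Ebf1 heterozygous cells, and 8.51, 13.1, 12.41, 12.93 and 14.33 in leukemia. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Of the identifiers, 27 were date serial numbers, as spreadsheets make from gene symbols, and were not named. Symbols were matched to GENCODE M21 for 21981 genes (95.3%). Reads of overlapping or antisense genes and of close paralogs could not be told apart.

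Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the libraries of a comparison were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided, only the 2 groups compared), adjusted by Benjamini and Hochberg and called at an adjusted p under 0.05. The 38 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Figures and tables used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes Pax5 and Ebf1, the 8 highest and 8 lowest called genes with at least a 2-fold change, 5 FPKM and no overlap of groups, leaving out immunoglobulin and T cell receptor segments, symbols that start with Gm and digits, end in Rik or contain -ps, and small RNA genes (Mir, Snor, and Rn followed by a digit), and the 2 genes of smallest p (4 where over 10 members passed) in lists that camera called or with at least 3 members past the threshold.

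On simulated reads with 200 changed genes at a dispersion of 0.05, limma recovered 69% of 2-fold and 95% of 4-fold changes for leukemia against wild type (10969 genes), 57% and 99% for Ebf1 heterozygous against wild type (11179 genes), and 75% and 97% for leukemia against Ebf1 heterozygous (11145 genes). These shares hold for that dispersion only, since no difference shared across the genes of a library was simulated. Real Ebf1 heterozygous libraries correlated at 0.893 to 0.944 with each other, and wild-type libraries at 0.956 to 0.984. Replicate numbers were checked for pairing by correlating deviations from group means. For wild type and Ebf1 heterozygous these were 0.65, 0.32 and 0.69 for numbers 1, 2 and 3, each over 0.1, so the numbers were taken to pair these samples. Deviations from the mean of 3 libraries are not independent of each other. The pairing is therefore an assumption that these values do not test. The labels state no shared day or batch. None of the 55 pairs of libraries, within or between groups, agreed within sampling noise. The closest pair was wild-type replicate 2 and Ebf1 heterozygous replicate 2, with a chi-square per gene of 12 and a correlation across genes of up to 0.989 between these groups, against at most 0.984 within a group. A mislabelled library is not ruled out, which bears on every comparison with the Ebf1 heterozygous group.

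Alternatives were another pseudocount, other filters, quantile and median-ratio scaling, all groups in 1 fit, array weights, robust eBayes, a 2-fold minimum, a replicate block and leaving out each replicate. Voom on the recovered reads, Ebf1 heterozygous replicate 2 alone (1 library, assumed to vary like the other group), and the block and left-out replicates for the lists were added after the data were seen. The deposited table held 0 immunoglobulin heavy or light chain genes and 0 mitochondrial genes, so the planned comparison of Ighv gene shares was not run, and the FPKM values are relative to totals without these genes.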

Results

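RNA levels were measured by sequencing in 11 mouse libraries from C57BL/6 mice. Progenitor B cells were purified on columns from bone marrow, as 3 wild-type libraries and 3 libraries of mice with 1 functional Ebf1 copy (Ebf1 heterozygous), each from a pool of mice. The 5 leukemia libraries came from lymph node cell suspensions of single mice heterozygous for both Pax5 and Ebf1. Pax5 and Ebf1 are transcription factors that establish and maintain B cell identity. Library totals in units of 1e6 reads ran from 8.51 to 15.31, so that 1 read on a transcript of 2000 bases was worth 0.033 to 0.059 FPKM. All folds below are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values are from limma.

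Both targeted genes fell in leukemia, and neither passed the test in Ebf1 heterozygous cells. Pax5 (chromosome 4, 44524757 to 44710487, GRCm38) averaged 222 ± 77.9 FPKM in wild type (SD, n = 3), 179 ± 83.5 in Ebf1 heterozygous cells (n = 3) and 119 ± 38.3 in leukemia (n = 5). Ebf1 (chromosome 11, 44617317 to 45008091) averaged 99.1 ± 14.3 FPKM in wild type, 71.2 ± 24.1 in Ebf1 heterozygous cells and 66.6 ± 10.8 in leukemia. Against wild type, the leukemias held 53.5% of the Pax5 level and 67.2% of the Ebf1 level (two-sided exact permutation p = 0.0179 for each, the smallest that 5 against 3 libraries can give). In Ebf1 heterozygous cells Ebf1 stood at 71.8% of wild type (exact permutation p = 0.3), where 3 against 3 libraries cannot give a p below 0.1. A table of gene levels gives no allele, so the values do not show how much RNA each copy made.

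**Figure D1:**
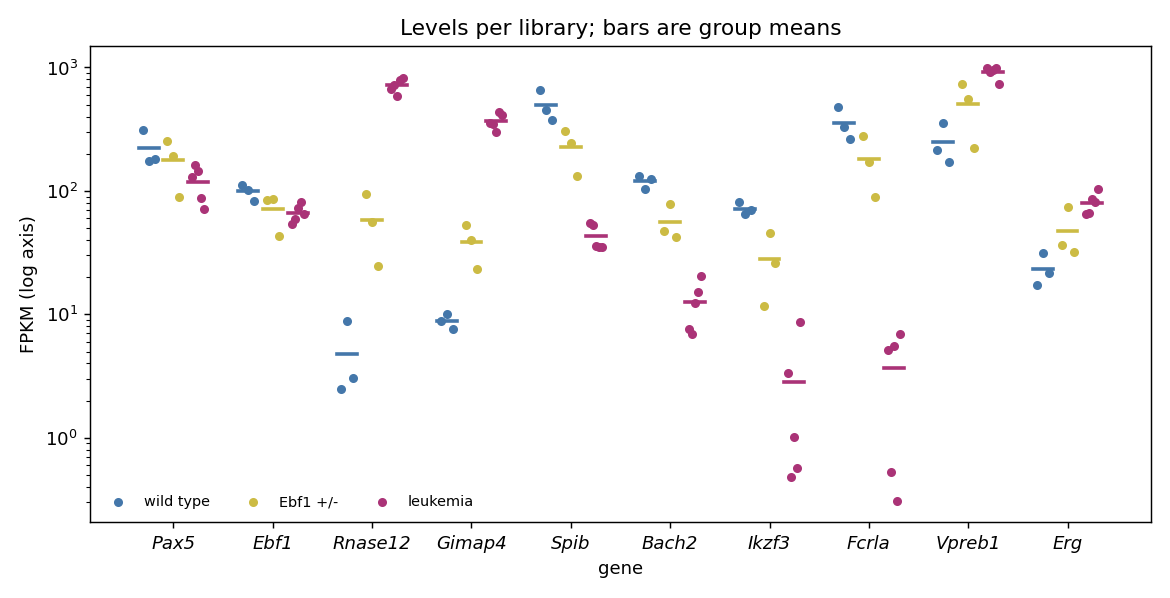
FPKM on a log axis of 10 genes in each library, as points for 3 wild-type, 3 Ebf1 heterozygous and 5 leukemia libraries, with bars at the group means. Rnase12 averaged 4.78, 58.3 and 720 FPKM in the 3 groups, and Spib 494, 228 and 42.8.

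The first comparison asked how leukemic cells differ from normal progenitor B cells. Leukemias carried far more Rnase12, a member of the ribonuclease A family (chromosome 14, 51056698 to 51057661), at 720 ± 95.3 FPKM (SD, n = 5) against 4.78 ± 3.51 in wild type (n = 3). Gimap4, a GTPase of lymphocytes (chromosome 6, 48684549 to 48692060), stood at 370 ± 54.4 against 8.81 ± 1.18 FPKM. Among the named genes, Spib, Ikzf3 and Fcrla went the other way. Spib, an Ets family transcription factor, fell from 494 ± 142 to 42.8 ± 10.2 FPKM, Ikzf3, the lymphoid regulator Aiolos, from 71.9 ± 7.92 to 2.82 ± 3.48, and Fcrla, an Fc receptor-like protein of B cells, from 356 ± 110 to 3.68 ± 3.04.

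Of 10968 genes tested, limma called 2267 higher and 2647 lower in leukemia, a balance that quantile scaling turned to 2632 higher and 2385 lower, with 17 sign changes among the calls. Of the calls on the deposited scale, 726 and 939 changed by at least 2-fold. The 2 groups did not overlap for 46.3% of genes, where chance gives 3.57%. Besides Rnase12 (log2 fold change 7.11, SE 0.30, adjusted p = 1.8e-06) and Gimap4 (5.23, SE 0.14, adjusted p = 9.05e-08), the highest under the naming rule were Cdh17, a cadherin (5.06, SE 0.41), Scin, an actin-severing protein (4.10, SE 0.70), Trem1, a receptor better known from myeloid cells (4.03, SE 0.21), Ston1 (4.03, SE 0.19) and Gimap3. Gm525, a symbol that the rule leaves out, named here after its values were seen, stood at 322 ± 268 FPKM against 1.09 ± 0.278 (6.59, SE 0.88). Rnase11 rested on 3 wild-type reads, a ratio of 317 with a counting interval of 108 to 1540. Genotype, leukemic state, tissue, cell purification and the pooling of mice differed together here, so no part of these differences can be assigned to any of them.

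Genes that Pax5 activates were lower as a group in leukemia. Of 21 tested, 11 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00955, and adjusted p = 0.587 with an estimated correlation). Besides Spib and Ikzf3, Bach2, a transcriptional repressor, fell from 120 ± 14.6 to 12.5 ± 5.64 FPKM and Irf8, an interferon regulatory factor, from 104 ± 24.4 to 19.4 ± 10.9. The fall was not particular to this list, whose median log2 fold change was -1.04. Of 6 B lineage genes in neither the Pax5 nor the Ebf1 list, 4 fell and 1 rose (median -1.36). Those 6 were set apart after the values were seen. Among 10 genes that Pax5 represses, 5 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.13), including Emb, a cell adhesion protein, from 17.1 ± 3.41 to 77.7 ± 7.22 FPKM, and Ly6a, the stem cell antigen Sca-1, from 8.53 ± 3.67 to 91.4 ± 56.1. Ebf1-activated genes split, with 6 lower and 3 higher of 13 (camera adjusted p = 0.44). Vpreb1, part of the surrogate light chain of the pre-B cell receptor, was among those higher, at 918 ± 108 FPKM against 247 ± 93.9, while Pik3ap1, an adaptor of B cell signalling, fell from 172 ± 21.5 to 23.5 ± 8.25.

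Of 22 genes altered recurrently in B-cell acute lymphoblastic leukemia, 13 fell and 4 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.0477, and adjusted p = 0.509 with an estimated correlation). The list was not called by camera with pseudocount 0.1 (0.0552). Its adjusted p ranged from 0.00027 by fry, which tests against no change rather than against other genes, to 0.509 by camera with an estimated correlation. Ikzf1, the lymphoid regulator Ikaros, fell from 220 ± 8.8 to 96.4 ± 3.46 FPKM. Tcf3, which encodes E2A, fell from 338 ± 61.8 to 82.8 ± 20.1, and the cell cycle inhibitor Rb1 from 33.4 ± 0.545 to 7.59 ± 2.48. Erg, an Ets factor of early progenitors, rose from 23.4 ± 7.43 to 80.4 ± 15.8.

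Signalling genes moved in both directions. Of 10 MAPK feedback and target genes, 6 rose and 2 fell (camera adjusted p = 0.147), among them Dusp4, a phosphatase that acts on MAP kinases, from 0.358 ± 0.0857 to 5.01 ± 1.39 FPKM, and Etv5, an Ets factor, from 5.55 ± 0.592 to 19.4 ± 4.51. The RAS and MAPK components themselves had 8 members lower and 0 higher of 15 (camera adjusted p = 0.131). STAT5 target genes split evenly, 5 higher and 5 lower of 14 (camera adjusted p = 0.876): Socs2, a cytokine signalling inhibitor, rose from 5.49 ± 0.978 to 47.3 ± 17.2 FPKM and the survival gene Bcl2l1 fell from 67.6 ± 16.9 to 14.6 ± 5.65. Of 13 homing and adhesion genes, 2 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.343), and among those lower Cd44 fell from 39.7 ± 4.91 to 1.88 ± 1.52 FPKM.

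Growth genes separated by kind. Of 21 Myc and ribosome biogenesis genes, 18 rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 4.8e-07, and adjusted p = 0.609 with an estimated correlation), with the nucleolar protein Nop56 at 178 ± 13.7 against 86.7 ± 13.5 FPKM and Cdk4, a kinase that drives cell cycle entry, at 406 ± 17.5 against 208 ± 36.6. Of 21 mitosis genes, 19 fell and 0 rose, or 20 and 0 adjusted over the list alone (camera adjusted p = 4.8e-07, and adjusted p = 0.587 with an estimated correlation). Ube2c, which acts in mitotic exit, went from 272 ± 35.7 to 126 ± 13.6 FPKM and the mitotic kinase Plk1 from 97.3 ± 14.3 to 52.1 ± 5.34. DNA replication genes did not fall with them. Of 22, 18 had positive values, and 3 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.131). Glycolysis genes had 10 members higher and 3 lower of 16, the same adjusted over the list alone (camera adjusted p = 0.0159, and adjusted p = 0.587 with an estimated correlation). The ribosomal protein genes rose in 26 of 26 cases, the same adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 3.03e-10, and adjusted p = 0.587 with an estimated correlation). Under median-ratio scaling 26 of 26 rose (median 0.79, camera adjusted p = 7.27e-10). Under quantile scaling 10 of the 26 rose, 19 had positive values and the list was no longer called (median 0.24, camera adjusted p = 0.0575). Of the RNA quality list, where only Malat1 and Neat1 were measured, 1 fell, or 2 adjusted over the list alone (median log2 fold change -0.92).

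Granulocyte, platelet and erythroid markers were lower in the leukemias. All 13 granulocyte markers tested fell (median log2 fold change -5.59, camera adjusted p = 1.56e-09, and adjusted p = 0.509 with an estimated correlation), as did 8 of 8 megakaryocyte and platelet markers (adjusted p = 5.59e-05, and adjusted p = 0.587 with an estimated correlation) and 7 of 8 erythroid markers (adjusted p = 7.5e-05, and adjusted p = 0.509 with an estimated correlation), or 13, 8 and 8 adjusted over the list alone. The medians of the last 2 lists were -2.98 and -3.57, or -5.24 and -3.82 with genes at 0 reads in a group set to their bound. Mpo, a granule enzyme of neutrophils, stood at 120 ± 17.5 FPKM in wild type and 0.0447 ± 0.0137 in leukemia. Car1, a carbonic anhydrase of red cells, had 0 reads in the 5 leukemias against 304 ± 255 FPKM in wild type, which makes it at least 8360-fold lower when 3 reads over the group are taken as the floor. Camera called no other cell type list. Of 6 monocyte markers 3 fell and 1 rose (adjusted p = 0.301), among them Lyz2, the lysozyme of myeloid cells, which fell from 382 ± 118 to 84.6 ± 52.8 FPKM, and of 5 dendritic cell markers 4 fell and 0 rose (0.094). Of 3 lymph node stromal markers 2 fell (0.148), the 1 mast cell marker measured fell, 1 NK cell marker of 4 rose and 1 fell (0.851), and of 11 T cell markers 2 rose and 1 fell (0.966). S100a9, an abundant granulocyte transcript, ranged from 120.08 to 1199.44 FPKM between the 3 wild-type pools.

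**Figure D2:**
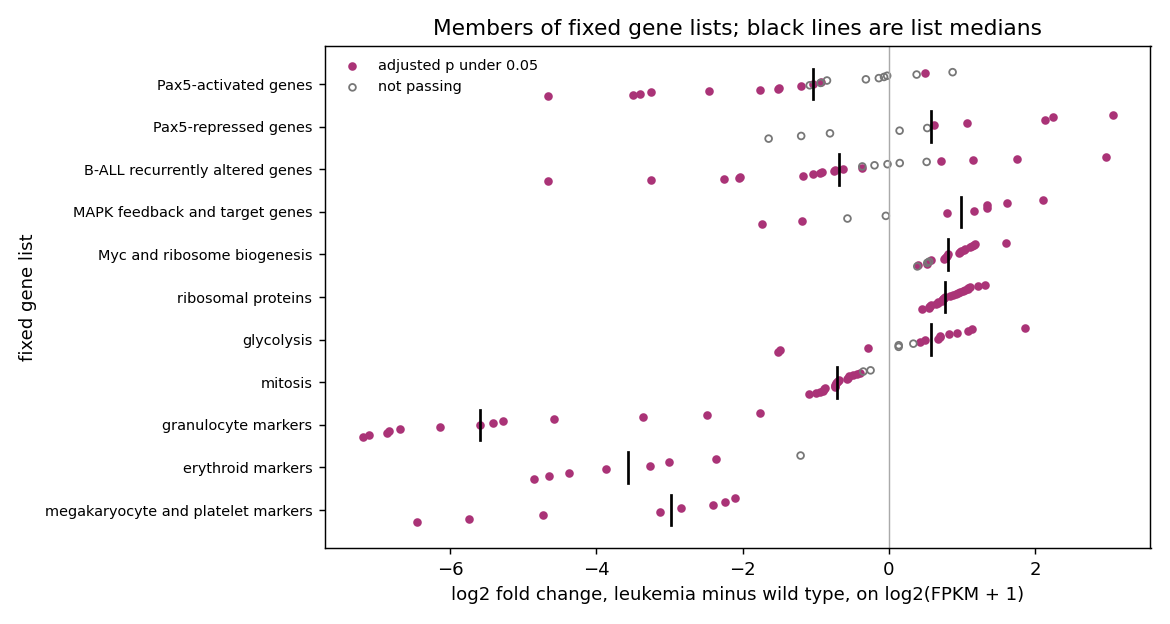
Log2 fold changes of leukemia minus wild type, on log2(FPKM + 1), for the members of 11 gene lists. Filled points passed limma's adjusted p threshold of 0.05, open points did not, and black lines mark list medians, which run from -5.59 for granulocyte markers to 0.98 for MAPK feedback genes. Under quantile scaling the ribosomal protein median falls to 0.24.

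The Pax5 difference between leukemia and wild type (log2 fold change -0.91, SE 0.30, limma adjusted p = 0.0338) lost its call without wild-type replicate 1 (adjusted p = 0.138), without leukemia replicate 4 (0.0647), with no filter (0.0552) and with all groups in 1 fit (0.0702) and with the replicate block (0.129), over a range of 0.0219 to 0.138. The Ebf1 difference (-0.57, SE 0.15, adjusted p = 0.0132) lost its call without wild-type replicate 1 (0.0553) or 2 (0.051) and with all groups in 1 fit (0.063), over a range of 0.00729 to 0.063.

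The second comparison set progenitor B cells of mice with 1 functional Ebf1 copy against wild type, from the same tissue. The listed alignment tools also differ with the group. The share of other marrow cells may differ between pools: marker genes of such cells are given below, but the share itself was not measured. No difference below can therefore be assigned to the Ebf1 copy alone. No gene passed the threshold of limma, in either direction, among 11167 tested. Large differences can have gone uncalled: Rnase12, at 58.3 ± 35 against 4.78 ± 3.51 FPKM, had a limma adjusted p of 0.228. Granulocyte markers had 14 of 14 positive values (median log2 fold change 1.45, camera adjusted p = 2.01e-05, and adjusted p = 0.753 with an estimated correlation), with a median of 0.54 without wild-type replicate 3, 0.67 without Ebf1 heterozygous replicate 1 and at most 2 without any other library. Megakaryocyte and platelet markers had 8 of 8 positive values (median 1.21, camera adjusted p = 0.0873), but 1 of 8 without Ebf1 heterozygous replicate 3 (median -0.14), so that library carried their direction. Their median was 0.6 without wild-type replicate 1 and 2.14 without Ebf1 heterozygous replicate 1. S100a9 reached 3681.48 FPKM in Ebf1 heterozygous replicate 1, and Ppbp, a platelet chemokine, reached 2034.04 FPKM in replicate 3, against at most 1199.44 and 223.46 in wild type.

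At an unadjusted p under 0.05 limma had 863 genes, 468 higher and 395 lower, and the smallest adjusted p was 0.0552. Groups did not overlap for 15.6% of genes, where chance gives 10% if the 6 libraries are exchangeable, which leaves their pairing out. Voom on recovered reads also called 0 genes, with 857 at an unadjusted p under 0.05. Wild-type and Ebf1 heterozygous libraries with the same number deviated together, and those numbered 2 were closer than any pair within a group, so a mislabelled library is not ruled out. With the replicate block the count of calls was again 0, and 1800 genes had an unadjusted p under 0.05.

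Several B cell genes had values between wild type and leukemia without passing the test. Bach2 averaged 56.2 ± 19.6 FPKM against 120 ± 14.6 in wild type (log2 fold change -1.12, SE 0.25, limma adjusted p = 0.388), and Ikzf3 27.9 ± 17.2 against 71.9 ± 7.92 (-1.52, SE 0.44, adjusted p = 0.478). Emb stood at 46.3 ± 15.1 against 17.1 ± 3.41 FPKM (1.35, SE 0.28, adjusted p = 0.332). It passed in the fit with all groups (adjusted p = 0.0477, range 0.0477 to 1). As lists, Pax5-activated genes had 2 of 20 positive values (camera adjusted p = 0.00778), Pax5-repressed genes 11 of 12 (0.00142) and the recurrently altered leukemia genes 6 of 21 (0.000312). The Pax5-repressed median of 0.661 did not lie between wild type and leukemia, where it was 0.573 over 10 genes. That list shares Csf1r and Ccr2 with the monocyte markers and Cd28 with the T cell markers. Both marker lists were also called higher here, so RNA of other cells may add to it, which was not tested. The Pax5-activated list was not called without Ebf1 heterozygous replicate 3 (0.814) or without wild-type replicate 1 (0.137), over a range of 0.000332 to 0.904. Adjusted over the list alone, 1 Pax5-repressed gene passed and 0 in the other 2 lists. None of these calls held with an estimated correlation (adjusted p = 0.753 for each), nor by fry.

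Camera called 14 lists in this comparison. Higher values also prevailed among glycolysis genes (16 of 16 positive, adjusted p = 2.01e-05), NK cell markers (10 of 10, 0.000312), ribosomal proteins (26 of 26, 0.00112), monocyte markers (0.00137), interferon-stimulated genes (0.00704), T cell markers (0.0255), Myc genes (0.0255) and oxidative phosphorylation genes (0.0403), and lower values among mitosis genes (0.00821) and NF-kB targets (0.0475). None was called with an estimated correlation (adjusted p = 0.753 or 0.8). Quantile scaling ended the calls of ribosomal proteins, with 14 of 26 positive (adjusted p = 0.631), oxidative phosphorylation (0.1) and NF-kB targets (0.0554), pseudocount 0.1 that of NF-kB targets (0.0572), and the 5 FPKM filter that of T cell markers (0.128). Calls were also lost on leaving out 1 library: Myc genes without wild-type replicate 1 (0.892) or Ebf1 heterozygous replicate 2 (0.155) or 3 (0.391), mitosis genes without wild-type replicate 2 (0.271) or Ebf1 heterozygous replicate 3 (0.32), and ribosomal proteins and interferon-stimulated genes without Ebf1 heterozygous replicate 1 (0.0849 and 0.0978). Oxidative phosphorylation was lost without wild-type replicate 1 (0.137) or 3 (0.0826) or Ebf1 heterozygous replicate 1 (0.418). NF-kB targets were lost without wild-type replicate 1 (0.232) or Ebf1 heterozygous replicate 2 (0.16) or 3 (0.32), and T cell markers without wild-type replicate 2 (0.122) or Ebf1 heterozygous replicate 1 (0.0849) or 3 (0.153). With the replicate block, oxidative phosphorylation was no longer called (0.0679), while Ebf1-activated genes were called lower (0.0295), and stem and early progenitor genes (0.0193), MHC class II genes (0.0145), megakaryocyte markers (0.00425) and mast cell markers (0.0091) higher. By camera with an estimated correlation and no block, none of these added lists was called (adjusted p from 0.753 to 0.832).

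The third comparison set the leukemias against progenitors that also lack 1 Ebf1 copy. Pax5 genotype, leukemic state, tissue, purification, pooling and the listed alignment tools differed together here, so no difference can be assigned to any of them. Cdh17 (43.7 ± 29.1 against 0.431 ± 0.136 FPKM, n = 5 and 3), Ston1 (24.3 ± 5.92 against 0.842 ± 0.597) and Cacna1h, a calcium channel subunit (12.8 ± 5.06 against 0.116 ± 0.0409), averaged under 1 FPKM outside leukemia. Rnase12 remained 13.8-fold higher in leukemia, over an Ebf1 heterozygous level of 58.3 ± 35 FPKM. Pax5 (log2 fold change -0.52, SE 0.37, limma adjusted p = 0.342) and Ebf1 (-0.04, SE 0.23, adjusted p = 0.911) did not pass.

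Limma called 1039 genes higher and 1370 lower of 11161, with 357 and 817 changed at least 2-fold. The 2 groups did not overlap for 29.1% of genes, where chance gives 3.57%. Pax5-activated genes had 7 members lower and 0 higher of 21, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.546 with an estimated correlation), with Spib at 42.8 ± 10.2 against 228 ± 88.9 FPKM. This list was not called without Ebf1 heterozygous replicate 1 (0.11) or 2 (0.0786), over a range of 0.000142 to 0.546. MAPK feedback genes had 4 higher and 0 lower of 9, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0217, and adjusted p = 0.495 with an estimated correlation), again with Etv5 (19.4 ± 4.51 against 4.23 ± 0.813 FPKM) and Dusp4 (5.01 ± 1.39 against 0.69 ± 0.853). That call was lost with the replicate block (0.0731), without Ebf1 heterozygous replicate 1 (0.116) and without leukemia replicate 2 (0.0758), 4 (0.0996) or 5 (0.0931), over a range of 0.0036 to 0.495. Myc and ribosome biogenesis genes rose in 14 of 21 cases, 18 adjusted over the list alone (adjusted p = 7.04e-09, and adjusted p = 0.495 with an estimated correlation), and mitosis genes fell in 11 of 21, 12 adjusted over the list alone (2.39e-05, and adjusted p = 0.546 with an estimated correlation). Of 22 DNA replication genes, 18 had positive values and 0 passed (camera adjusted p = 0.12). Ribosomal protein genes rose in 10 of 26 cases, 16 adjusted over the list alone (9.55e-08, and adjusted p = 0.546 with an estimated correlation), and in 6 under quantile scaling (0.0305). Cdkn2a, a cell cycle inhibitor locus, stood at 12.7 ± 8.09 against 0.237 ± 0.0969 FPKM (limma adjusted p = 0.0029). Its call was lost with voom (0.0648), where the log2 fold change was 5.29, over a range of 0.000623 to 0.0873.

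Granulocyte, erythroid and platelet markers fell again: 13 of 13 granulocyte (adjusted p = 1.74e-16, and adjusted p = 0.299 with an estimated correlation), 8 of 8 erythroid (8.37e-08, and adjusted p = 0.495 with an estimated correlation) and 8 of 8 megakaryocyte markers (2.34e-05, and adjusted p = 0.546 with an estimated correlation). In this comparison 5 of 8 NK cell markers fell as well (0.0217, and adjusted p = 0.546 with an estimated correlation). Dendritic cell markers fell in 5 of 6 cases (0.00148, and adjusted p = 0.541 with an estimated correlation), and of 7 monocyte markers 4 fell and 1 rose (0.0287, and adjusted p = 0.495 with an estimated correlation). The NK call was lost without Ebf1 heterozygous replicate 1 (0.734) or 3 (0.436), without leukemia replicate 4 (0.0514), with the replicate block (0.0564) and with a 5 FPKM filter (0.509), and the monocyte call without Ebf1 heterozygous replicate 1 (0.0889) or 3 (0.133). Without Ebf1 heterozygous replicate 3 the counts were 690 higher and 1007 lower, and quantile scaling turned the split to 1568 higher and 1120 lower.

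Leukemia and Ebf1 heterozygous cells were both compared with the same wild-type libraries. No gene was called in both by limma, since the Ebf1 heterozygous comparison had no calls (863 at an unadjusted p under 0.05, and 0 calls by voom). Taking Ebf1 heterozygous genes at an unadjusted p under 0.05, 268 were higher in both and 320 lower in both among 10669 genes, where independent lists would share 82.8 and 95.8. The log2 fold changes had a covariance across genes of 0.106, against 0.0322 on average in 100 simulations of unchanged groups with shared controls, a difference of 0.0733. Genes were simulated as independent and libraries as unpaired, so these values are no measure of what real shared libraries can give. Their correlation across genes was 0.317 against 0.42 in the simulations. The 3 wild-type libraries are too few to be split, so part of the overlap may come from sharing them.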

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

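The tests of other marrow cells and of scaling were chosen after the result was seen. Among 116 named genes tested over the 5 leukemias, 7 had a library that stood apart from the others by Dixon's criterion, where chance gives about 5.8; not all of them are named here. Siglech, a marker of plasmacytoid dendritic cells, was 7.9 FPKM in leukemia replicate 1 and at most 0.408 in the others (gap over range 0.905). Vpreb1 was lowest in replicate 5, at 733 against 919 FPKM (0.732). Itga2b was highest in replicate 3 at 0.117 FPKM on 5 reads (0.866). Cd34, Elane and Pf4 each had 1 or 2 reads in a single leukemia and 0 in the others, which fixes the ratio at 1.

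S100a9, at 120.08 to 1199.44 FPKM in the 3 wild-type pools, was an abundant transcript among them. Granulocyte, platelet and erythroid markers were lower in leukemia by a median of 4.62 on the log2 scale over 28 genes (-4.62). Scaling between libraries is argued against, since the median nearest to 0 under 2 other scalings was -4.48. RNA of other marrow cells in the wild-type pools stays open: the markers had a median ratio of 6.63 between the highest and lowest pool, against 1.54 for 95 genes of the B lineage lists, but they did not vary together. Mean log2 scores were 6.68, 5.91 and 4.6 in replicates 1, 2 and 3 for granulocyte markers and 2.55, 4.08 and 4.82 for platelet markers, while Mpo (120 ± 17.5 FPKM) and Elane (70.7 ± 7.94) hardly differed between pools. Column purification may leave such cells, and tissue and purification differ with the leukemic state, so the marker loss says nothing certain about the leukemic cells themselves.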

How the results depend on the processing

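Voom, Ebf1 heterozygous replicate 2 alone, and the block and left-out replicates for lists were chosen after the data were seen. Of 160 called results on named genes, 0 reversed, 42 lost the call under at least 1 alternative, and 12 of these on leaving out a replicate. For leukemia against wild type, a 2-fold minimum left 726 higher and 939 lower, leaving out a replicate gave 1746 to 2135 higher and 2048 to 2590 lower, and 4556 calls were shared with quantile scaling, which turned the balance to 2632 higher and 2385 lower. For Ebf1 heterozygous against wild type, pseudocount 0.1 gave 1 higher and 2 lower, median-ratio scaling 0 and 2, all groups in 1 fit 11 and 11, and leaving out a replicate 0 to 4 and 0 to 1. For leukemia against Ebf1 heterozygous, quantile scaling gave 1568 higher and moved the median of all genes from -0.0248 to 0.0793, array weights gave 504 and 896, no filter 2148 lower, a 5 FPKM filter 881 lower (fewer genes tested), a 2-fold minimum 357 and 817, replicate 2 alone 231 and 338 (1 library, so a fall follows from the number alone), and leaving out a replicate 690 to 1224 and 1007 to 1416. Lists called fell from 9, 14 and 11 in the 3 comparisons to 0, 0 and 0 with an estimated correlation. Fry called 19, 0 and 16. Leaving out a replicate gave 9 to 12, 11 to 19 and 9 to 14 lists, and replicate 2 alone 8 in the Ebf1 comparison. Genes called in both comparisons with wild type were 0, or 588 at an unadjusted p and 3 with pseudocount 0.1. Apart from the smaller gene sets and sample numbers, the cause was not tested.

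Leukemia numbers did not pair with the others: same-number correlations were -0.05, 0.07 and -0.13 with wild type and 0.03, 0.06 and -0.1 with Ebf1 heterozygous. With the replicate block, leukemia had 1658 higher and 2020 lower than wild type, and 350 and 594 against Ebf1 heterozygous. In the comparison of Ebf1 heterozygous with wild type, taken as paired, the block gave 0 and 0 gene calls and 18 lists, and changed no other call than those named beside the lists. The rescaling without immunoglobulin genes was not run.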

Other observations

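Tests of scaling for the ribosomal genes, of leukemic RNA, of the shared wild-type libraries and of cell stage were chosen after the result was seen, as were the genes named here outside the fixed rule. In the fit with all groups, 22 genes were called between Ebf1 heterozygous and wild type, 11 higher and 11 lower, and all 22 were called in the same direction in leukemia. Both comparisons share the wild-type libraries, which favours a common direction, and no value for unchanged groups was computed for this count. Reln, a secreted glycoprotein, stood at 0.613 ± 0.17 FPKM (SD, n = 3) against 14 ± 4.66 in wild type and 0.0105 ± 0.00902 in leukemia. Ets2 stood at 3.77 ± 0.207 against 16.2 ± 2.24 and 0.721 ± 0.547, and Arntl, a circadian clock gene, at 24.4 ± 6.61 against 61.1 ± 8.36 and 5.31 ± 0.442. On the higher side were Igfbp4 (78.1 ± 5.09 against 27.6 ± 5.74 and 167 ± 26.5), Gimap4 (38.7 ± 14.7 against 8.81 ± 1.18) and Rnase12 (58.3 ± 35 against 4.78 ± 3.51). Ckap4 (17.6 ± 3.76 against 7.38 ± 1.14 and 10.8 ± 0.992) and 4930597A21Rik (28.1 ± 22.5 against 0.0431 ± 0.0746 and 3.6 ± 3.23) stood above leukemia. None of the 22 passed with only the 2 groups in the fit.

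Many Ebf1 heterozygous values lay between wild type and leukemia, though not all, as granulocyte markers had medians of 1.45 and -5.59 in the 2 comparisons, and 3 explanations were weighed. Shared wild-type libraries alone stay open. The covariance of 0.106 lay above the highest simulated value of 0.0365. The simulations drew each gene on its own and without the pairing of numbers. Their range therefore leaves out deviations that the genes of a library share, and cannot decide this. The correlation of 0.317 lay below the simulated mean of 0.42, but it also falls as differences of leukemia alone add spread, while shared libraries add to the covariance itself. Leukemic RNA in the Ebf1 heterozygous libraries stays open, apart from 11 lower genes given below. Over 9 genes near absent from wild type, the median share of 4.53% met neither bound set for it beside 7.49% for Rnase12. In 4 of the 9, the highest Ebf1 heterozygous library stayed under the level needed to match Rnase12. Cdh17 (0.528 against 1.85 FPKM) and Rnase11 (0.375 against 1.35) were well under it, Gm525 (3.6 against 3.95) and Ston1 (1.52 against 1.93) narrowly. The others reached it. The needed level assumes that leukemic RNA has the same profile throughout. Under that assumption, a share of 7.49% could lower a gene only slightly. With all groups in 1 fit, the 11 genes called lower than wild type had log2 fold changes from -1.05 (Fam63b) to -3.17 (Reln). These values argue against leukemic RNA as the cause for those 11 genes, which that fit picked out. A shift from pre-B to pro-B stage cells may contribute: the median log2 change from wild type of 8 pro-B genes exceeded that of 8 pre-B genes by at least 1.55 in the 3 numbered pairs, although Sox4 among the pro-B genes was lower in all 3, but these genes were chosen with the pattern in view, so the test cannot separate it from an effect of Ebf1 dose or of the different alignment tools listed for this group, which was not tested.

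Ribosomal protein genes were higher in leukemia by a median of 0.76. A gene length trend and a GC content trend are argued against as the whole cause, since the median was 0.69 and 0.89 after each was removed, with median absolute deviations of 0.17 and 0.18. Fewer other cells in leukemia stay open. B lineage core genes had a median of -0.96, and -1.36 for the 6 in neither the Pax5 nor the Ebf1 target list. A fall of these genes within leukemic cells would hide a rise from fewer other cells, so they cannot decide this. Normalization between libraries stays open: the median was 0.79 under median-ratio scaling and 0.24, with a deviation of 0.22, under quantile scaling. A change in these genes and a scaling effect cannot be told apart, because these scalings differ in their answer.

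Relabelling the libraries tested chance for the gene counts. For leukemia against wild type, 1 of 56 splits, the real one, gave as many as its 4914 calls, the smallest share that 56 splits can give. The highest other split gave 2. Every other split mixes leukemia with wild type, which adds their difference to the spread and lowers the count, so 2 is not a chance level. For leukemia against Ebf1 heterozygous, again 1 of 56 splits reached 2409, and the highest other gave 3, with the same limits. For Ebf1 heterozygous against wild type, all 10 of 10 splits gave 0 calls, the highest other included, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 863 genes and the highest other 1427, a split of wild-type replicates 1 and 2 with Ebf1 heterozygous replicate 1 from the other libraries, which points to a structure of the samples. Among the 4 splits that part all 3 pairs, the highest other gave 55.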
